A study of Vitis vinifera with 12 samples.

How the data were processed

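Gene expression was measured by RNA sequencing in the fruit of the grapevine (Vitis vinifera) table-grape cultivar Victoria. Fruit was sampled at 40, 50, 60 and 80 days after full bloom, with 3 libraries (a, b and c) per age and 12 libraries in all. Per the labels' protocols, polyadenylated RNA was purified with oligo(dT) beads and made into directional libraries. The same protocols say that RNA was extracted separately from several biological replicates and that the replicates were then pooled. Whether libraries a, b and c of an age come from separate berries or from 1 pool is therefore not settled by the labels, and p-values measure only the spread between these libraries, which may be technical.

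The authors deposited 1 table with an FPKM value (fragments per kilobase of transcript per 1000000 fragments) for each of 22580 gene IDs in each library. The submitters' processing notes name Trimmomatic 0.36, FastQC, TopHat2, Cufflinks and edgeR, without saying what each was used for. The genome build, the annotation and the settings are not given in the sources used here. Of the deposited IDs, 21791 have the VIT_ form of the grapevine reference annotation, and 789 are called newGene with a number. No further scaling between libraries is recorded, and the FPKM columns sum to between 1058844 and 1395232. All 12 columns were matched to a sample by its description in the labels, and 0 columns were left over.

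The table pairs no ID with a gene name. None of its IDs matched the reference gene table used here (0 matches, assembly ASM3070453v1), so genes are given by ID and no function is stated. For this reason the 32 gene lists fixed before the data were examined, which were to be found by product name (photosynthesis, cell wall, sugar and acid metabolism, flavonoids, hormones, seed, vascular and cuticle markers among them), could not be filled or tested. The rule for genes to be named asked for an informative name, which no ID has. The other criteria of that rule were kept for the comparison of 40 with 80 days, and only the 2 largest rises and the 2 largest falls are printed. Those criteria were both test thresholds, a mean of at least 10 FPKM in the higher group, and no overlap between the 3 libraries of one age and the 3 of the other.

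FPKM values are not counts, so no count model was fitted. Values were transformed to log2(FPKM + 1), where 1 is the pseudocount, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 libraries were tested, 14743 in all. A linear model with 1 mean per age was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, 8 residual degrees of freedom). Genes were called when the Benjamini-Hochberg adjusted p was under 0.05 and the difference was at least 1 on the log2 scale. A moderated F test over the 4 ages used the same thresholds, with the range of the 4 means as the size. Data were simulated from the means and spreads of the same 14743 genes for the comparison of 40 with 80 days. The fit recovered 82.3% of genes whose FPKM was changed by 1.5 on the log2 scale, 82.9% of those changed by 2 and 91.2% of those changed by 3. It called 3 of 14543 unchanged genes. The simulated noise was normal, independent between genes and of equal spread in all libraries, and far fewer genes changed than the data call. These rates need not hold for the real comparison.

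Absolute depth is not known from an FPKM table. In genes listed at low values, the ratio between libraries clustered at steps as whole fragments give. The main cluster of these ratios was used to estimate each library's depth relative to library a at 40 days. This estimate ranged from 0.85 in library c at 40 days to 1.74 in library a at 50 days. Its cluster was least sharp in library c at 60 days (0.897), where it stood 2.57 times above the background of ratios. The median standard error of a difference between 2 ages was 0.15 on the log2 scale. Exact zeros in such a table can be failed estimates and are reported as listed at 0. No column was identical to another; without counts, replicates could not be compared with counting noise.

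Summaries per library (the share of summed FPKM in the most abundant genes, and the effective number of genes, which is the exponential of Shannon's entropy of the FPKM shares) were compared over the 4 ages by exact permutation, over all 15400 ways to part 12 libraries into 4 groups of 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-of-ratios scaling, scaling to a sum of 1000000, the replicate letter as a block, sample weights, no intensity trend, no minimum fold, only the 2 groups compared, and each library left out in turn.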

Results

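The transcriptome of Victoria grape berries was followed over 4 ages, 40, 50, 60 and 80 days after full bloom, with 3 libraries per age. The series was designed to describe berry development, and its design text speaks of a pair of cultivars. Only Victoria was analysed here. In each library between 17710 and 18359 of the 22580 gene IDs had a value above 0. Between 13526 and 14078 reached 1 FPKM. The estimated depth of the libraries relative to each other lay between 0.85 and 1.74, and the absolute depth is unknown.

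Libraries grouped by age and were ordered by age. Within an age the Pearson correlation of log2(FPKM + 1) over the tested genes was between 0.972 and 0.990. Between 40 and 50 days it was 0.921 to 0.936, between 50 and 60 days 0.954 to 0.967, between 60 and 80 days 0.926 to 0.949, and between 40 and 80 days 0.836 to 0.870. The first principal component held 54.6% of the variance and placed the ages in order. The second (17.8%) set the 50-day and 60-day libraries apart from the youngest and the oldest berries. Library c at 40 days and library a at 80 days lay furthest from the others of their age, with SDs of their deviations from the age mean of 0.29 and 0.30 on the log2 scale, against 0.19 to 0.27 in the other 10 libraries.

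**Figure D1:**
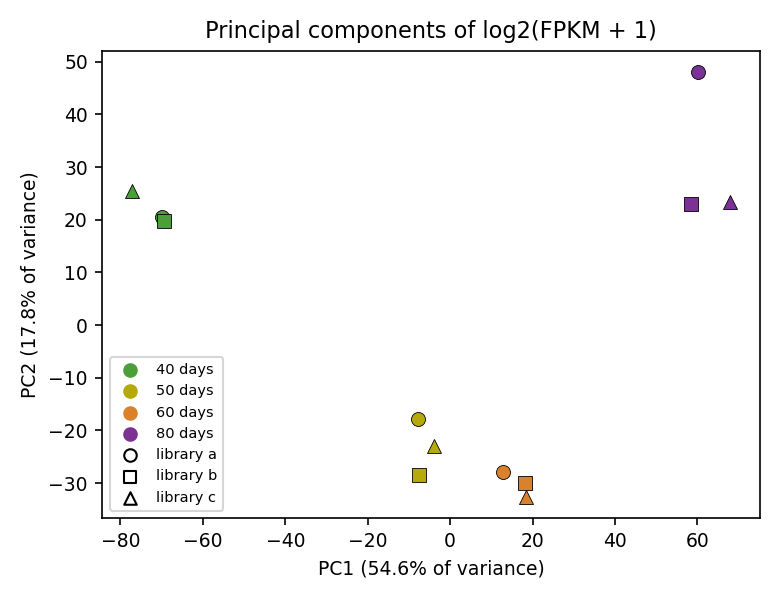
First and second principal components of log2(FPKM + 1) over the 14743 tested genes, with 1 point per library, colour for age in days after full bloom and shape for the library letter. On the first component (54.6% of the variance) the ages lie in order without overlap, while library a at 80 days lies apart on the second (48.1, against 22.9 and 23.3 for b and c).

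The share of the transcript pool held by the 10 highest genes rose with age. The 10 highest genes of a library held 22.8% ± 0.86 (SD, n = 3) of its summed FPKM at 40 days, 30.4% ± 2.0 at 50 days, 34.5% ± 1.2 at 60 days and 38.4% ± 2.0 at 80 days. The effective number of genes fell from 1323 ± 108 at 40 days to 913 ± 117, 729 ± 58 and 550 ± 56 at the later ages. On the deposited values, genes with at least 10 FPKM numbered 8687 ± 38 at 40 days and 7957 ± 17 at 80 days, though counts at a fixed FPKM depend on the scaling. The share of the single highest gene did not follow this course, with 9.14% ± 0.61 at 40 days and 7.04% ± 0.92, 6.95% ± 0.26 and 8.24% ± 0.85 at the later ages. It differed among the 4 ages (exact permutation p = 0.019, adjusted 0.025), while the libraries of 40 and 80 days overlapped (exact p = 0.2). Genes of at least 1000 FPKM numbered 103 ± 14 at 40 days and 101 ± 9.6 at 80 days, with no difference past the test (exact p = 0.21, adjusted 0.25). The share of the 10 highest genes, the effective number and the number of genes of at least 10 FPKM differed among the 4 ages by the exact permutation test (p = 6.49e-05, the smallest that 15400 partitions can give, and 0.00014 after Benjamini-Hochberg adjustment over 13 measures). The number of genes above 0 did not pass that test (exact p = 0.37). Comparing 40 with 80 days alone, 3 libraries against 3 cannot give an exact two-sided p below 0.1.

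Of the 10 genes with the highest mean over all libraries, 9 had a higher mean at 80 than at 40 days and 1 a lower mean. These genes were ranked on a mean that includes the 80-day libraries, in each of which they were the 10 highest, against 6 of the 10 highest in each 40-day library. The ranking therefore favours rises. In 8 of the 9 and in the falling gene, the libraries of the 2 ages did not overlap; the 10% of genes that chance alone separates is no yardstick for genes picked in this way. The mean of the remaining gene was 1.19 times as high at 80 days, less than the 1.21 times by which the summed FPKM of the libraries was higher, so its direction depends on the scaling. The falling gene went from 102850 ± 14141 FPKM at 40 days to 27342 ± 4159 at 80 days. The largest relative rise among the 10 was from 5254 ± 1419 to 108340 ± 14987 FPKM. Without these 10 genes the effective number was 2968 ± 177 at 40 days and 2599 ± 115 at 80 days, a ratio of 0.88 in place of 0.42 with them. Part of that move is built in, since less of the top is removed at 40 days. Without each library's own 10 highest genes the numbers were 3197 ± 197 and 2599 ± 115, a ratio of 0.81.

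**Figure D2:**
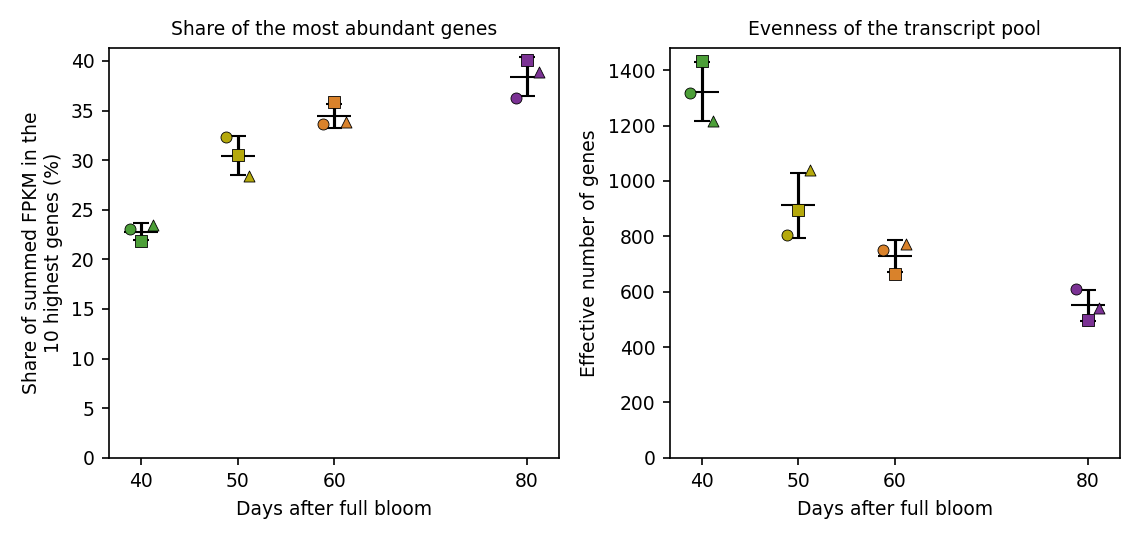
Left, the percent of summed FPKM held by the 10 highest genes of each library, and right, the effective number of genes, against days after full bloom; points are libraries, and bars are the mean ± SD of 3. The share rises from 22.8% to 38.4% while the effective number falls from 1323 to 550.

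Between the youngest and the oldest berries, 40 and 80 days, 3411 of 14743 tested genes (23.1%) changed. More of them fell (2370) than rose (1041). The changes downward were also the larger ones: 324 genes fell by at least 3 on the log2(FPKM + 1) scale and 78 rose by as much. The genes that rose held 6.61% ± 0.88 of the summed FPKM at 40 days and 36.9% ± 1.7 at 80 days, while those that fell went from 32.0% ± 1.2 to 7.10% ± 0.38. These sets were chosen on the same libraries, so the shares describe the calls and do not test them.

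Of the genes that met the criteria for naming, 678 were higher and 1577 lower at 80 days. On the scale used, the largest rise was that of VIT_14s0068g01400, although VIT_14s0171g00100 was above it with a pseudocount of 5 (6.37 against 6.36) and without library b at 40 days (7.84 against 7.81). VIT_14s0068g01400 was at 0.961 ± 0.33 FPKM at 40 days (n = 3), 45.6 ± 28 at 50 days, 45.6 ± 22 at 60 days and 486 ± 63 at 80 days (log2 difference 7.96 ± 0.44 SE, limma adjusted p = 1.05e-07). It rose from 40 to 50 and again from 60 to 80 days. VIT_14s0171g00100 was at 2.59 ± 1.8, 6.12 ± 1.8 and 2.42 ± 0.32 FPKM at 40, 50 and 60 days, and reached 624 ± 173 FPKM at 80 days (7.48 ± 0.38 on the log2 scale from 60 to 80 days, limma adjusted p = 8.72e-07). The largest fall was that of VIT_04s0008g05640. Its values at 40 days were 333, 317 and 669 FPKM, its mean was 8.39 ± 7.5 at 50 days and 0.459 ± 0.17 at 60 days, and at 80 days it was listed at 0.142, 0 and 0 (log2 difference -8.63 ± 0.46 SE, limma adjusted p = 8.85e-08). VIT_03s0063g02380 also fell mainly before 50 days, with 133, 151 and 392 FPKM at 40 days, 0.522, 1.56 and 12.4 at 50 days, and 0.267, 0.412 and 0 at 80 days (-7.36 ± 0.66 SE, limma adjusted p = 3.32e-06). Library c held the highest of the 3 values at 40 days in both falling genes.

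**Figure D3:**
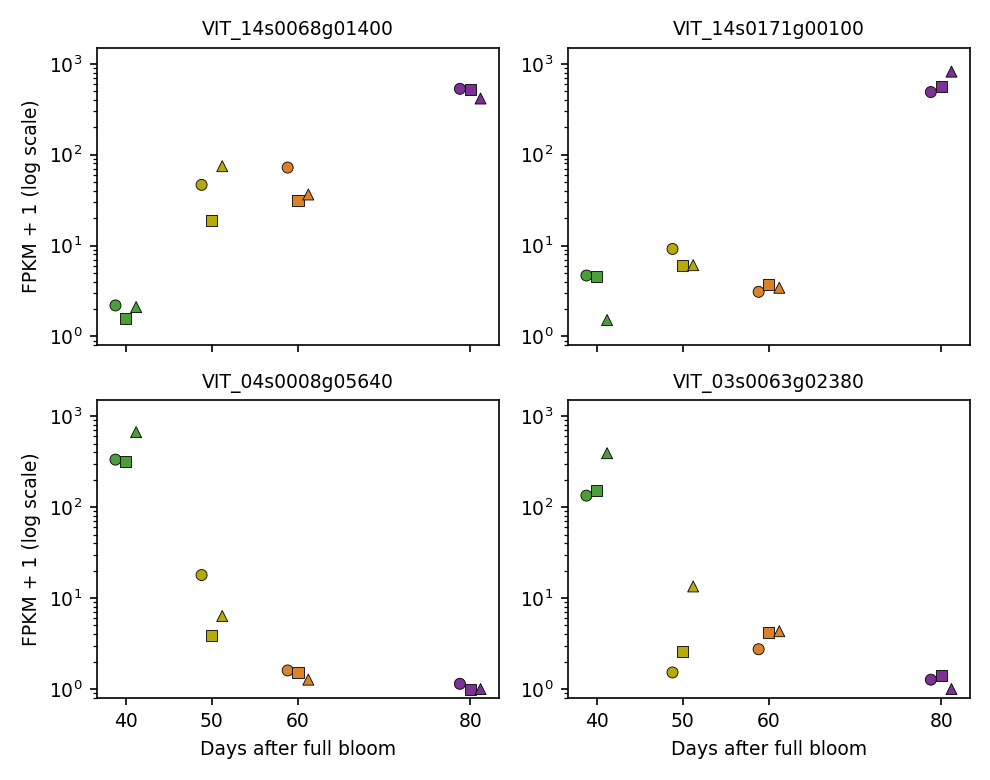
FPKM + 1 on a log axis against days after full bloom for the 2 genes with the largest rise (upper panels) and the 2 with the largest fall (lower panels) from 40 to 80 days; each point is a library. VIT_14s0171g00100 is at a mean of 6.12 FPKM or less up to 60 days and of 624 FPKM at 80 days, while VIT_04s0008g05640 falls from values of 317 to 669 FPKM at 40 days to 16.9 FPKM or less at 50 days.

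The balance of rises and falls from 40 to 80 days depended on how libraries were scaled. On the deposited values the median tested gene changed by -0.11 on the log2 scale, and 30.5% of the called genes rose. Median-of-ratios scaling sets changes relative to the median gene (median -0.0049), and gave 1263 rises and 2119 falls (37.3% rises). With each library scaled to a sum of 1000000 the median was -0.35, and 700 genes rose while 3000 fell (18.9% rises). Falls outnumbered rises in each case. The number called was 2011 with a pseudocount of 5 and 8870 with no minimum fold.

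The first interval, 40 to 50 days, changed 1750 genes (11.9% of those tested). Falls predominated, with 1243 genes lower and 507 higher at 50 days. Among them 252 genes fell and 83 rose by at least 2 on the log2 scale, and the median size of a called change was 1.39. Much of the long-term change was already present at 50 days: genes higher at 80 than at 40 days had a median of 44.0% of their log2 difference by then (quartiles 19.9% and 65.5%), and genes lower at 80 days had 52.9% (quartiles 28.9% and 75.9%). These genes were selected on the same 40-day and 80-day libraries. Chance values at 40 days can raise both shares, and those at 80 days can lower them. VIT_04s0008g05640 and VIT_03s0063g02380 changed in this interval by -5.77 ± 0.46 SE and -5.74 ± 0.66 SE on the log2 scale (limma adjusted p = 9.15e-06 and 7.15e-05). VIT_14s0171g00100 also passed the thresholds upward in this interval (1.13 ± 0.38 SE on the log2 scale, limma adjusted p = 0.031), but lost the call in 7 of 24 alternatives, among them leaving out library c at 40 days (0.60, limma adjusted p = 0.063) or library a at 50 days (0.93, limma adjusted p = 0.11). The count was 899 with a pseudocount of 5 and 6429 with no minimum fold.

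From 50 to 60 days 637 genes (4.32%) passed the thresholds, with rises and falls nearly in balance, 297 higher and 340 lower. Only 43 of the rises and 63 of the falls reached 2 on the log2 scale. VIT_04s0008g05640 fell again (-2.39 ± 0.46 SE on the log2 scale, limma adjusted p = 0.0051), while VIT_14s0068g01400 and VIT_03s0063g02380 did not pass the test in this interval (0.11 ± 0.44 and -0.03 ± 0.66 on the log2 scale). Which direction prevailed hung on the scaling: median-of-ratios scaling gave 322 rises and 321 falls, and scaling to a sum of 1000000 gave 226 and 413. The number called was 299 with a pseudocount of 5 and 2852 with no minimum fold.

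In the last interval, 60 to 80 days, which is 20 days long where the others are 10, 1398 genes (9.48%) changed. Falls again outnumbered rises, 1003 against 395. Of these, 220 genes fell and 78 rose by at least 2 on the log2 scale, and the median size was 1.44. VIT_14s0171g00100 rose most here, and VIT_14s0068g01400 rose by 3.48 ± 0.44 SE (limma adjusted p = 0.00015). A pseudocount of 5 gave 735 genes, and no minimum fold gave 5137.

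**Figure D4:**
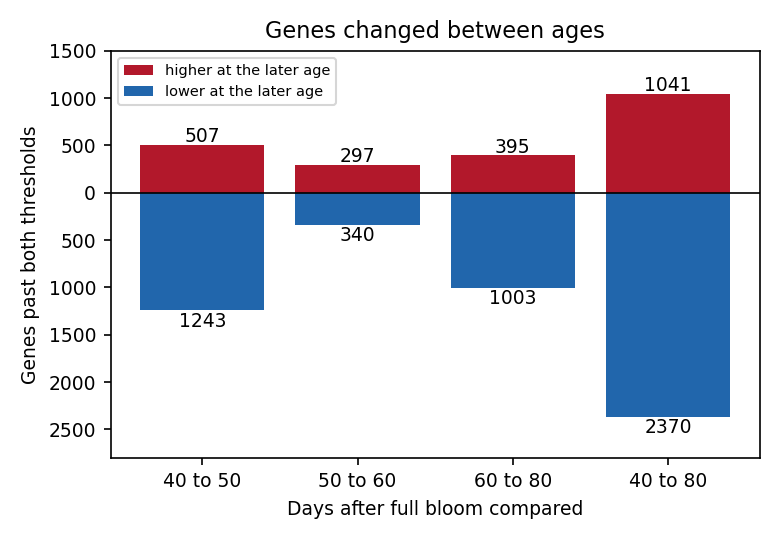
Number of genes past both thresholds (limma adjusted p under 0.05 and a log2 difference of at least 1) in each comparison; bars above 0 count genes higher at the later age, and bars below 0 count genes lower at the later age. The interval from 50 to 60 days has the fewest (297 and 340), and falls outnumber rises in all 4 comparisons on the deposited values; with median-of-ratios scaling the 50 to 60 day balance is 322 rises and 321 falls.

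In the test over all 4 ages, 4507 genes differed by the moderated F test of limma. For 2385 of them (52.9%) the highest mean was at 40 days, for 513 (11.4%) at 50 days, for 657 (14.6%) at 60 days and for 952 (21.1%) at 80 days. The means fell at every step in 1158 genes and rose at every step in 518. In the other 2831 the steps had mixed signs. These classes use only the sign of each step, without a test, so a small chance difference can count as a turn. Scaling to a sum of 1000000 left 595 genes with their highest mean at 80 days.

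Changes in the first and the last interval, which have no library in common, overlapped in several directions. Both come from 1 fit with 1 spread per gene, so a gene of small spread is more readily called in each. The numbers for independent lists given below are therefore a reference and no chance level. Of the 1243 genes lower at 50 than at 40 days and the 1003 lower at 80 than at 60 days, 259 were the same, where 84.6 would be shared by independent lists. Rises in both numbered 58 (13.6 for independent lists), rises followed by falls 71 (34.5), and falls followed by rises 38 (33.3). Among changes from 50 to 60 days, a change in the opposite direction followed more often than one in the same direction. Of the 297 genes that rose from 50 to 60 days, 118 fell from 60 to 80 days and 20 rose further (20.2 and 7.96 for independent lists). Of the 340 genes that fell from 50 to 60 days, 69 rose and 36 fell further (9.11 and 23.1 for independent lists). From 40 to 50 and 50 to 60 days, which share the 50-day libraries, both continued changes and reversals were above the independent-list values by similar factors: of the genes that rose first, 40 rose again and 42 fell (10.2 and 11.7 for independent lists), and of those that fell first, 71 fell again and 62 rose (28.7 and 25). The later pair of intervals shares the 60-day libraries, whose chance values push a gene's changes in opposite directions. In 20 simulations with unchanged ages the mean number shared was 0, because almost no gene is then called, so this gives no chance level for genes that do change. Part of the excess may come from the shared libraries. Splits with separate libraries, given next, remove only the chance values of single libraries. A deviation common to all libraries of the shared age stays in both intervals and still pushes changes in opposite directions. With separate 60-day libraries in each interval (6 splits, 1 library in one interval and 2 in the other), rises followed by falls numbered 53 to 95, and 4.46 to 6.69 times the number for independent lists. Further rises numbered 5 to 32, and 1.24 to 4.51 times that number. The 32 came in the split with library a alone in the later interval (7.1 for independent lists), where 94 genes rose and then fell (21.1). Falls followed by rises numbered 21 to 43, and 4.06 to 7.86 times the number for independent lists. Further falls numbered 14 to 60, and 1.01 to 2.48 times that number. Further falls were the more frequent (60 against 33) in the split with library a alone in the later interval (24.2 and 8.14 for independent lists). With separate 50-day libraries, the medians over 6 splits were 33 genes that rose again and 24.5 that rose and then fell, and 61 that fell again and 32.5 that fell and then rose. The factors over independent lists were then less alike. They were 3.82 to 4.68 for rising again and 2.27 to 4.35 for rising and then falling. For falling again they were 2.57 to 3.42, and for falling and then rising 1.47 to 2.07.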

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

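Of the alternatives here, leaving out library c at 40 days and library a at 80 days together, leaving out the 10 most abundant genes or the 10 highest of each library, and using separate 50-day or 60-day libraries in each interval, were chosen after seeing the data. Counts kept within 1.5 times their value, in every comparison and direction, without a filter, with a filter at 5 FPKM, with median-of-ratios scaling, with sample weights, without an intensity trend, in fits of only the 2 groups compared, and without any single library. Without those 2 libraries there were 3337 genes for 40 to 80 days, of which 2979 were among the 3411. Of the 3411, 3160 were also called with median-of-ratios scaling and 3044 with scaling to a sum of 1000000. For 40 to 80 days the sign and call of the 4 named genes held under the 24 alternatives run on them. In the shorter intervals, VIT_14s0171g00100 lost its call from 40 to 50 days in 7 of 24. Calls were gained in 8 cases: from 60 to 80 days by VIT_03s0063g02380 (4) and VIT_04s0008g05640 (1), and from 50 to 60 days by VIT_14s0171g00100 (3, downward). From 50 to 60 days, differences far from the threshold changed sign: VIT_03s0063g02380 was at 0.22 with a pseudocount of 0.1, 0.21 with sample weights, and between -0.68 and 0.89 with single libraries left out, and VIT_14s0068g01400 was between -0.44 and 0.56 with single libraries left out; the cause was not tested. Scaling to a sum of 1000000 moved 1 count by more than 1.5 times, the genes highest at 80 days (595).

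The pseudocount and the minimum fold moved counts by more. With a pseudocount of 5, 899 genes changed from 40 to 50 days (238 higher, 661 lower), 299 from 50 to 60 days (127 and 172), 735 from 60 to 80 days (221 and 514) and 2011 from 40 to 80 days (610 and 1401). It left 2621 genes differing among the ages, with the highest mean at 40, 50, 60 and 80 days in 1407, 292, 335 and 587. It left 104 genes that fell in both the first and the last interval, 52 that rose from 50 to 60 and then fell, and 31 that fell and then rose; a larger pseudocount shrinks the fold of low genes by construction. A pseudocount of 0.1 gave 419 genes that fell in both the first and the last interval, and a lowest within-age correlation of 0.960. With no minimum fold, the calls were 6429 from 40 to 50 days (2514 higher, 3915 lower), 2852 from 50 to 60 days (1311 and 1541), 5137 from 60 to 80 days (2271 and 2866) and 8870 from 40 to 80 days (3507 and 5363). The test over all ages then gave 10776 genes, highest at 40, 50, 60 and 80 days in 4754, 1645, 1507 and 2870, with 1035, 490 and 405 genes in the 3 interval patterns above. Without the 10 most abundant genes the effective number of genes at 80 days was 0.8755 of that at 40 days, and without the 10 highest of each library 0.8128. With separate 60-day libraries the genes that fell from 50 to 60 days and then rose numbered 37 (median of 6 splits with fewer libraries per interval).

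Deviations of same-letter libraries correlated between -0.16 and 0.19 across ages, and 6 of 12 libraries correlated best with their own letter. No chance level was computed for these values. Whether the letters a, b and c pair libraries across ages is therefore not settled. With the letter as a replicate block the counts were 1760, 628, 1393 and 3404 genes in the 4 comparisons. The gene lists planned at the start, and so their alternatives (camera with an estimated correlation, fry, other scaling, pseudocount and block), were not run because the IDs have no names here. The unknown depth limits what can be said of genes listed near 0.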

Other observations

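Of the tests of explanations here, the one for RNA of younger berries in library c and the one for median-of-ratios scaling were chosen after their results were seen.

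On the deposited values, more genes went from abundant to near 0 than the reverse, and other scalings were not tried for these counts. With fewer than 1 FPKM in all 3 libraries of one age and at least 10 FPKM in all 3 of the other, 59 genes were on at 40 and off at 80 days, and 12 were off at 40 and on at 80 days. Each of these was also past the thresholds of the main test, which adds little, since the criteria demand a large difference in the same libraries. With at least 100 FPKM in the higher age, 5 were switched off and 1 was switched on. The newGene loci, which the VIT_ annotation does not hold, were expressed at lower levels (median 3.33 against 13.9 FPKM). They changed from 40 to 80 days at 25.4% (83 of 327), against 23.1% of VIT_ genes (Fisher's exact test, p = 0.32, 0.43 after adjustment over 4 comparisons). No chromosome, as read from the chromosome field of the VIT_ IDs, held more or fewer risen or fallen genes than the rest after adjustment over 40 Fisher's exact tests; the smallest adjusted p was 0.16, for fewer risen genes on chromosome 7 (4.55% against 7.11% elsewhere).

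Genes with neighbouring VIT_ IDs (the same scaffold, with numbers at most 10 apart) changed together more often than chance. Among 7654 neighbouring pairs, 309 were called in the same direction from 40 to 80 days, against a mean of 235 and a maximum of 279 in 1000 shuffles within chromosomes (one-sided permutation p = 0.001, the smallest these shuffles can give, and 0.003 after adjustment over 3 tests). There were 27 runs of at least 3 neighbours against 17.6 in shuffles (permutation p = 0.024, adjusted 0.036), 6 of them risen and 21 fallen. The longest run, of 5 genes on chromosome 8, was no longer than shuffles often give (permutation p = 0.11). A risen run of 4 genes on chromosome 5 held 1.45% ± 0.54 (SD, n = 3) of the summed FPKM at 40 days, 9.77% ± 2.7 at 50 days, 13.5% ± 0.84 at 60 days and 16% ± 2.4 at 80 days. Nearly all of this came from 2 of its genes, both among the 10 most abundant, at means of 11178 and 5254 of 16576 FPKM at 40 days and 101340 and 108340 of 216830 at 80 days. A risen run of 4 genes on chromosome 19 went from 0.711% ± 0.12 to 3.92% ± 0.37, and 1 gene carried nearly all of it (8028 of 8044 FPKM at 40 days and 53138 of 53232 at 80 days).

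Reads shared between near-identical neighbours are a candidate explanation for such runs, since tandem copies are common in plant genomes. Fragments assigned to both genes would tie them together within an age as well, and the median within-age correlation of the 309 pairs was 0.186 (bootstrap SE 0.048), against 0.036 for random pairs called in the same direction. This is far below the 0.8 set for shared reads as the main cause, which 19 pairs (6.15%) passed, but above random pairs by more than the margin of 0.1 that would have argued against them. Joint regulation of neighbours would give the same correlation, so shared reads and regulation cannot be told apart here without the sequences.

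Falls outnumbered rises from 40 to 80 days, and a candidate explanation is that a few abundant rising genes take up the FPKM of the others. Median-of-ratios scaling left 37.34% of the called genes higher at 80 days (95% exact binomial interval 35.7% to 39%), from 30.5% on the deposited values. It removes that effect only if the median gene is itself unchanged. With no minimum fold 8870 of the 14743 tested genes were called, so an unchanged median gene is not assured. How much the effect accounts for is therefore not bounded by this scaling. Rises hidden at low values are a further candidate. With a pseudocount of 0.1, which shrinks low values less, 1318 genes were higher and 2754 lower (32.4% higher), so falls still outnumbered rises. A filter at 5 FPKM left 30.56% higher (28.8% to 32.3%), but it drops low genes and cannot uncover rises among them. These intervals treat genes as independent, which they are not. That more genes are turned down than up as these berries age stays open as a hypothesis, and RNA content per cell was not measured.

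Library c at 40 days stood apart from libraries a and b, and its lower depth (0.85 of library a) does not account for this, since among genes of at least 50 FPKM the SD of its log2 differences from a and b was 1.926 times that between a and b. RNA of older berries would put genes lower at 50 days below the other 40-day library. They were instead above it, by a median of 0.1043 (SE 0.026, with a median of 0.021 for all tested genes). Genes higher at 50 days were also above it (0.1798, SE 0.036), a shift towards their 50-day level, as RNA of older berries would give. That is the reverse of the 40 to 50 day change carried back to younger berries. Both SEs treat the genes of 1 library as independent, which they are not, and the 2 sets point different ways on older berries. RNA of older berries is therefore not settled. RNA of younger berries also stays open, since no library here is younger than 40 days to show what such berries express. Library c also lay further from the later ages on the first principal component (-77.1, against -69.8 and -69.5), and its correlations with the 80-day libraries were 0.836 to 0.858, against 0.851 to 0.870 for a and b. The correlations of library c with a and b of its own age were lower too (0.976 and 0.977, against 0.990 between a and b). Its lower correlations are therefore not particular to the 80-day libraries. Differences between plants, sampling or handling may remain and were not tested.

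For 40 to 50, 50 to 60, 60 to 80 and 40 to 80 days, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, with 1750, 637, 1398 and 3411 genes in the real splits and at most 1, 1, 1 and 3 in the others; 10 splits are too few for a share under 0.05. For the test over all ages, 1 of 100 splits of the 12 libraries, the real one, gave as many genes, with 4507 against at most 3011 in the others. The other splits mix ages within groups, so a difference between ages widens their spread and lowers their calls. Their numbers are therefore no level of false calls. If libraries a, b and c of an age come from 1 pool, the lead of the real splits shows only that same-age libraries are alike. It does not then tell an effect of age from chance differences between samplings.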
